A study of Homo sapiens with 3 samples.

How the data were processed

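Total RNA from MCF10A pools selected in 2 ug/ml puromycin was isolated, and 10 ug per sample was labelled during reverse transcription with Cy3 (wild-type PIK3CA) or Cy5 (PIK3CA H1047R), per the labels' protocols. Each of 3 arrays took both dyes, so every array is a paired comparison, and no array had the dyes swapped. The arrays were on 1 slide and in 1 scanning batch, so no batch could be tested. The labels call the arrays biological replicates and do not say whether the RNAs came from separate cultures; p-values then measure only the spread between these samples, which may be technical.

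Spot intensities (mean signal and median local background per dye) were written by Agilent Feature Extraction 10.10.1.1, per the file headers, while the submitters' processing notes name version 8.5.1.1. The files also hold Agilent's processed intensities, which were background-subtracted, detrended and dye-normalized by a linear factor and lowess, per the file headers, with surrogate values where a spot was not above background. The series table deposited by the authors gives log10 ratios of Cy5 over Cy3. Its values equal the log10 ratio column of the scanner files for the same features, with a largest difference of 1.7e-09 on the log2 scale, so that scale, direction and centring are known, and the median of each of its 3 columns is 0. The array grid was built on hg19 (GRCh37), per the file headers, and probe positions are given in that build.

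Each array held 62976 features, of which 4259 were controls and 58717 measured 50599 probes; 902 probes were printed 10 times. Intensities were read with the data.table package (version 1.17.8) and processed in limma 3.58.1 under R 4.3.3. Background was corrected with normexp and an offset of 50 on all spots, and each array was normalized by loess with controls and outlier spots at weight 0. The offset makes folds of dim probes smaller than they would be without it. Non-uniform and population-outlier spots, 399 to 402 features per array, were left out, control spots were left out, and the spots of a probe were averaged. A probe was well above background on an array where over 50% of its spots were, and it was tested if this held on all 3 arrays in at least 1 dye, which left 24343 probes. The spike-in controls of the scanner software had a slope of 0.837 to 0.842 between observed and designed log ratios, so the software's ratios are somewhat compressed. The intercept of the same fit was 0.129 to 0.131 on the log10 scale on the 3 arrays, an offset of the software's ratios above the designed ones. Slope and intercept were written by the software and were not computed for the loess ratios used here. Median signals were 47.0 to 48.4 in Cy3 and 73.0 to 76.6 in Cy5, over median backgrounds of 28.5 to 29.0 and 42.0 to 45.0.

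A gene was represented by its tested probe with the highest mean log2 intensity, which gave 18438 genes by name, 4362 of them with over 1 tested probe. Names were updated through the accession of each probe with a RefSeq gene table of assembly GRCh38.p14, used for names only; 13690 tested genes were named in this way, 14231 carried a RefSeq symbol, and the others kept the name in the files. Log2 ratios were fitted with limma (intercept only, eBayes) over the 3 arrays, and p-values were adjusted by Benjamini-Hochberg over the tested probes. Tests are two-sided. In all 12075 probes passed, 6302 higher and 5773 lower in H1047R. With 36 gene lists, all with at least 5 tested members, limma's camera was run with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, and with an estimated correlation and fry beside it. On 3 arrays the estimated correlation leaves the list test few degrees of freedom, so it has little power. For genes above background in 1 dye, a lower bound on the fold was set by the lowest signal among probes well above background, or by the dim probe's own signal where that was higher, on each array after loess and Aquantile normalization. The bound is a mean over the 3 arrays and makes no allowance for their spread.

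The genes named were set by a rule: PTX3 and PIK3CA; the 10 largest rises and 10 largest falls among genes past the threshold, above background in both dyes on all 3 arrays, with 1 sign on all 3 arrays and a regular gene symbol; up to 3 members of each list with the largest change among those past the threshold; and the 3 highest bounds in each direction among genes above background in 1 dye with a regular gene symbol. This rule, the gene lists, the tests and most alternatives were set before the data were examined. The alternatives were normexp without offset, no background correction, Agilent's processed signals, the series table, median centring, scale normalization between arrays, removal of a GC trend, no filter on dim probes, a filter in both dyes, keeping outlier spots, an intensity trend or robust eBayes, separate channels without the array as a block, leaving out each replicate, a 2-fold threshold, counts over probes, an estimated correlation and fry. A 1.5-fold threshold, limma's treat and lists without shared members were added after the data were seen. The fit and list test were tested on simulated data with the spread of the 24343 tested probes: changes of 1.2-fold, 1.5-fold, 2-fold and 4-fold were recovered in 54%, 74%, 88% and 100% of 50 probes each, 0.629% of calls were false, and 0 of 35 unshifted lists were called. The simulated probes were drawn independently and without dye bias, so false calls from correlated genes or from the dyes could not appear. Few probes were changed, against 51.5% of genes called in the data, so these rates do not carry over. Pairing of the dyes on an array comes from the labels, since each array holds both pools. Figures were drawn with matplotlib.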

Results

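Gene expression was compared between 2 stable pools of MCF10A, a non-tumorigenic human mammary epithelial cell line that the labels list as breast cancer. One pool carried a wild-type PIK3CA transgene and the other carried PIK3CA with the activating H1047R substitution. PIK3CA encodes the catalytic p110-alpha subunit of PI 3-kinase. The 3 two-colour arrays each held both pools, with wild type in Cy3 and H1047R in Cy5, and the labels call them biological replicates 1 to 3. The orientation was the same on all 3 arrays, so dye and genotype cannot be separated, and all ratios below are H1047R (Cy5) over wild type (Cy3). The series title names pentraxin-3 (PTX3) as a PI 3-kinase effector, and the comparison asks which transcripts differ between cells with the activated and the wild-type kinase. The series' design text names other cells and other replicate numbers than the sample labels, which were followed here.

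Each array held 62976 features, of which between 30687 and 30796 were well above background in Cy3 and between 30655 and 31149 in Cy5. No feature was saturated. Log2 ratios of 2 arrays correlated across the tested genes at r = 0.888 to 0.894 (genes are not independent replicates). The 3 arrays differed by about the sampling noise of their spots. For this test the mean of each spot position over the arrays was removed first. Among 606 probes printed 10 times, 4.29% then differed between arrays beyond the remaining noise between spots at F-test p under 0.05 (exact binomial 95% interval 2.82% to 6.22%), where 5% is the share given by noise alone. Without that step the share was 1.35% of 665 probes. They are counted as 3 replicates as labelled. If they were repeat hybridisations of 1 pair of RNA samples, they would count as 1 sample with no biological replicate check. The SDs and p-values below compare these RNA samples and may hold technical spread only, so the sizes of the changes are given first. The number of arrays limits the precision.

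PTX3 was 3.59-fold higher in H1047R cells (log2 ratio 1.84 ± 0.02, SD, n = 3; limma adjusted p = 2.34e-04). PTX3 encodes a secreted pattern recognition protein of the long pentraxin family. Its probe, for transcript NM_002852, lies at chromosome 3, 157160969 to 157161028 (hg19). It was among the 4 largest rises of any named gene and was positive on all 3 arrays. PIK3CA itself was measured by 2 probes that disagreed. The brighter probe, spanning 178948163 to 178951939 on chromosome 3, gave a log2 ratio of -0.13 ± 0.07 (SD, n = 3; limma adjusted p = 0.041). This call was lost without offset (-0.15), without the filter on dim probes and without replicate 1 or 3 (-0.11 each), and the sign turned with median centring (0.20). The second probe, at 178938816 to 178938875, was 1.71-fold higher in H1047R cells (log2 ratio 0.77 ± 0.12, SD, n = 3; limma adjusted p = 0.0011). Both pools carry a PIK3CA transgene, and which probes bind it was not tested, so PIK3CA was not used as a check of the labels. Exon and UTR positions of the probes were not assigned because no annotation of this genome build was used.

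The largest rises beside PTX3 included F3, KRT6B, INHBA and TGFBI, and the largest falls were those of KRT15, CAMK2B and PRR15L. F3, which encodes tissue factor, the cell-surface initiator of coagulation, rose 3.67-fold (log2 ratio 1.88 ± 0.04, SD, n = 3; chromosome 1, 94995080 to 94995139). KRT6B, a keratin of stressed and proliferating epithelia, rose 3.62-fold (log2 ratio 1.86 ± 0.01; chromosome 12, 52840556 to 52840615). The long non-coding RNA UCA1 rose 3.59-fold (1.85 ± 0.06). INHBA, the activin A subunit, rose 3.40-fold (1.76 ± 0.03), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 3.27-fold (1.71 ± 0.02). The matrix protein gene TGFBI rose 3.22-fold (1.69 ± 0.01) and CSF3, which encodes the granulocyte growth factor G-CSF, rose 3.18-fold (1.67 ± 0.10). EFR3B rose 3.14-fold (1.65 ± 0.13) and LCP1, the actin-bundling protein L-plastin, rose 3.05-fold (1.61 ± 0.05). KRT15, a keratin of basal epithelial cells, had a log2 ratio of -2.62 ± 0.04 (SD, n = 3), a 6.15-fold difference (chromosome 17, 39670142 to 39670201). CAMK2B, a calcium/calmodulin-dependent kinase subunit, fell 4.33-fold (-2.12 ± 0.05; chromosome 7, 44260428 to 44260487). PRR15L fell 3.64-fold (-1.86 ± 0.01) and KRT13, a keratin of stratified mucosal epithelia, fell 3.16-fold (-1.66 ± 0.05). The netrin receptor gene UNC5B fell 2.81-fold and GRHL3, a transcription factor of epidermal differentiation, fell 2.64-fold. VAV3, TMT1A, EPN3 and CLCA2 had log2 ratios between -1.33 and -1.38. The limma adjusted p of these 20 genes lay between 2.34e-04 and 3.97e-04, and each had 1 sign on all 3 arrays. Folds of dim genes are compressed by the background offset. With Agilent's own processed signals UCA1 was 10.3-fold higher, and CAMK2B and KRT13 were 7.99-fold and 5.25-fold lower. KRT6B is uncertain because near-identical KRT6 paralogs can bind its probe.

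**Figure D1:**
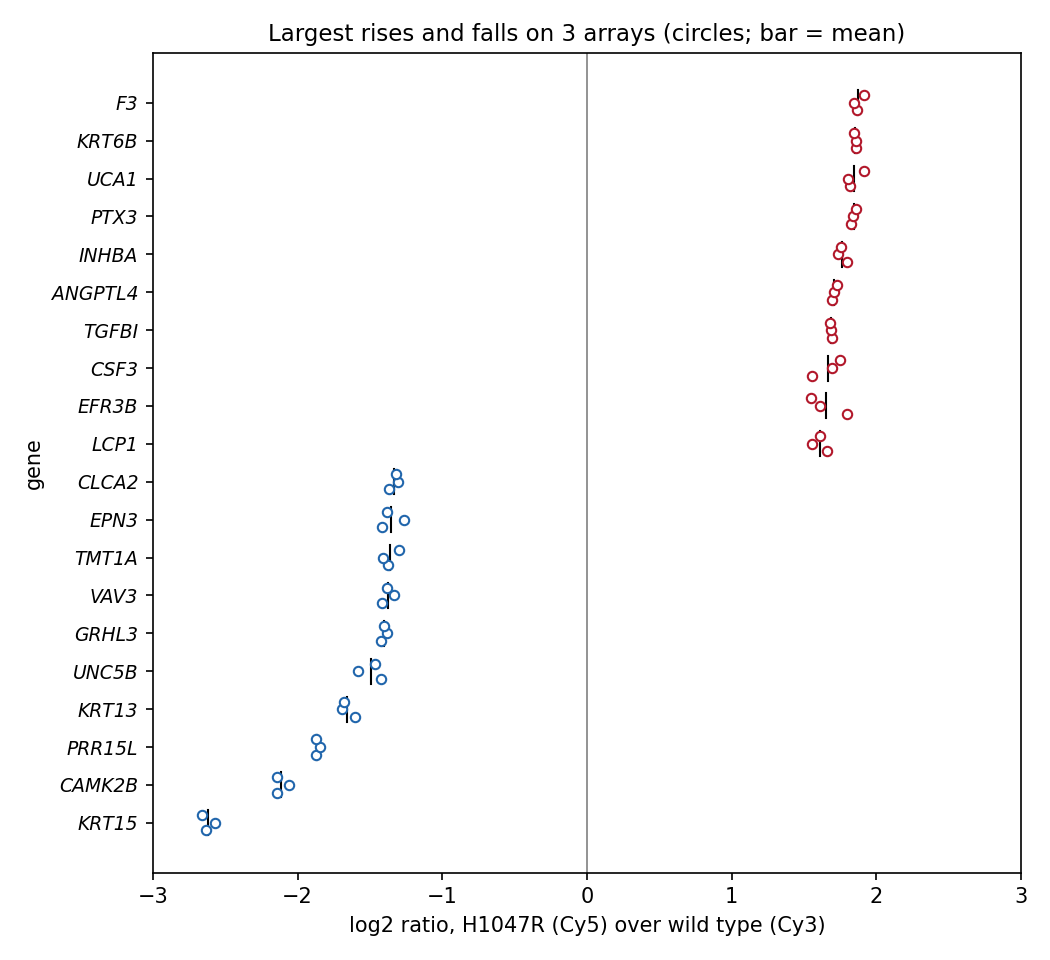
Log2 ratio of H1047R (Cy5) over wild type (Cy3) for the 10 genes with the largest rise and the 10 with the largest fall. Each circle is 1 of the 3 arrays and the black bar is their mean; the rises lie between 1.61 (LCP1) and 1.88 (F3) and the falls between -1.33 (CLCA2) and -2.62 (KRT15).

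Over all genes, the changes were many but mostly small. Of 18438 tested genes, 9495 passed limma's adjusted p threshold of 0.05, 4930 of them higher and 4565 lower in H1047R cells, and the median size of a called change was 0.20 on the log2 scale. At least a 2-fold change was seen in 101 genes, 68 higher and 33 lower. Of the called genes with a second tested probe at a position that did not overlap, the second probe had the same sign in 69.4% of 1587 genes called below 1.2-fold, 81.9% of 690 genes called at 1.2-fold to 1.5-fold and 90.8% of 131 genes called at 1.5-fold or more; these size limits were chosen after the data were seen. The share of calls that were higher was 51.9%, against 93.7% (13873 of 14803 genes) when arrays were median-centred without an intensity trend, which moved the median of all genes to 0.30. Loess centres the log2 ratios near 0 (median of tested genes 0.0086), so the near-even split follows largely from the normalization. Among named genes, median centring raised 18 bright ones by over 1.5 times, with TGFBI at a log2 ratio of 2.39, ANGPTL4 at 2.34, KRT7 at 1.86 and MT2A at 1.85. The 2-fold count was 239 with no offset (162 higher, 77 lower), 373 with Agilent's processed signals (235 higher, 138 lower) and 379 with median centring (368 higher, 11 lower). In 290 genes, called probes pointed in opposite directions. The second probes of called genes changed less than the first, which the choice of probes favours. The first probe was the brightest of its gene and had to pass the threshold. The second was dimmer, and the offset compresses dim probes. These ratios therefore cannot tell by how much the first probes overstate the changes. The median ratio of their log2 values was 0.404 for genes called below 1.2-fold, 0.418 at 1.2-fold to 1.5-fold, 0.513 at 1.5-fold to 2-fold and 0.57 at 2-fold or more. Below 1.2-fold, 538 second probes were called in the same direction and 161 in the opposite one, against 21 and 0 at 2-fold or more.

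TGF-beta target genes and inflammatory cytokine genes had the highest medians of the 36 gene lists, which were fixed before the data were examined, after loess; with median centring the ribosomal list was highest (0.99, against 0.77 for the cytokine and 0.70 for the TGF-beta list). Of 24 tested TGF-beta target genes, 20 rose and 0 fell, or 21 and 0 adjusted over the list alone, with a median log2 ratio of 0.52 (limma camera adjusted p = 1.03e-08; adjusted p = 0.263 with an estimated correlation). The risers in this list included ANGPTL4 and TGFBI. Of 27 NF-kB and inflammatory cytokine genes, 22 rose and 2 fell, or 22 and 3 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 8.37e-07; adjusted p = 0.263 with an estimated correlation). PTX3 and CSF3 led it, followed by CXCL1, a neutrophil chemokine, at 2.37-fold (1.25 ± 0.03), whose probe can bind related CXC chemokine transcripts. Of 22 YAP target genes, 14 rose and 2 fell, or 15 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.00123; adjusted p = 0.263 with an estimated correlation). F3, CCN1 (2.69-fold, 1.43 ± 0.07) and CCN2 (2.66-fold, 1.41 ± 0.10) led this list, and the last 2 encode secreted matricellular proteins. The list of RNA quality and stress genes was higher as well (median 0.24). Lists that share members are not independent: CCN2 is also a TGF-beta target and PTX3 is also listed under complement and acute phase genes.

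Epithelial junction genes were lower and mesenchymal genes higher in H1047R cells. Of 28 junction genes, 22 fell and 3 rose, with the same counts adjusted over the list alone and a median log2 ratio of -0.36 (limma camera adjusted p = 2.14e-06; adjusted p = 0.263 with an estimated correlation), which was -0.03 with median centring. The tight junction gene CLDN7 fell 2.04-fold (-1.02 ± 0.09), and the desmosomal cadherin genes DSG3 and DSC3 fell 1.93-fold (-0.95 ± 0.03) and 1.91-fold (-0.93 ± 0.11). Of 23 mesenchymal and EMT genes, 13 rose and 4 fell, or 14 and 4 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.00256; adjusted p = 0.263 with an estimated correlation). The risers included TGFBI and CDH11, a mesenchymal cadherin, at 2.06-fold (1.04 ± 0.16), which was 5.61-fold with Agilent's processed signals. This list missed the threshold with median centring (adjusted p = 0.0563), and RNA quality and stress genes were higher beside it (median 0.24). Lists of markers for cells other than epithelium did not pass. Of 7 fibroblast markers 1 rose (POSTN, 2.03-fold, or 3.75-fold with Agilent's processed signals) and 1 fell (FBLN1, -0.45, or 0.065 with median centring, where it did not pass). Of 8 blood cell markers 4 rose, led by PTPRC (1.85-fold) and CSF1R (1.42-fold), and 2 fell, led by CD14 (-0.91). Of 6 endothelial markers 2 rose, TEK (1.48-fold, or 2.44-fold with Agilent's processed signals) and ENG (1.13-fold), and 1 fell, PECAM1 (-0.57). These counts were the same adjusted over the list alone, and camera adjusted p was 0.994, 0.446 and 0.551.

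Targets of FOXO and p53 were lower. RNA quality and stress genes were higher in the same comparison (median 0.24). Of 26 FOXO target genes, 16 fell and 5 rose, or 18 and 5 adjusted over the list alone, with a median log2 ratio of -0.28 (limma camera adjusted p = 0.00163; adjusted p = 0.263 with an estimated correlation). FOXO factors are excluded from the nucleus when AKT, downstream of PI 3-kinase, phosphorylates them. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, fell 2.38-fold (-1.25 ± 0.01), TXNIP fell 1.73-fold (-0.79 ± 0.06) and BCL6 fell 1.68-fold (-0.75 ± 0.07). Of 29 p53 target genes, 18 fell and 7 rose, with the same counts adjusted over the list alone and a median of -0.24 (camera adjusted p = 0.0116; adjusted p = 0.265 with an estimated correlation). The pro-apoptotic gene BBC3 fell 1.85-fold (-0.89 ± 0.01), GDF15 fell 1.65-fold (-0.72 ± 0.02) and FDXR fell 1.49-fold (-0.58 ± 0.02); the call for FDXR was lost with median centring. With median centring, which moved the median of all genes to 0.30, the medians of the FOXO and p53 lists turned positive (0.052 and 0.16), and both lists still passed as lower than the other genes (adjusted p = 3.94e-06 and 0.0239). The list of PI3K pathway members did not pass (camera adjusted p = 0.110; 0.0297 as lower without the filter on dim probes), with 15 lower and 7 higher of 32 genes, or 16 and 7 adjusted over the list alone, and its median of -0.13 was 0.21 with median centring. Within it SGK1, a kinase related to AKT, fell 1.56-fold (-0.64 ± 0.02), PIK3R1, the p85-alpha regulatory subunit, had a log2 ratio of -0.40 ± 0.13 and lost its call with median centring, and IRS1, an insulin receptor adaptor, rose 1.71-fold (0.77 ± 0.02).

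Stress and chaperone genes rose, and antioxidant genes rose less clearly. Of 20 genes of RNA quality and stress, 14 rose and 3 fell, with the same counts adjusted over the list alone and a median log2 ratio of 0.24 (limma camera adjusted p = 0.00495; adjusted p = 0.263 with an estimated correlation). This list was chosen to show differences in RNA handling, and 4 of its 20 tested members are shared with other lists. The TGF-beta, NF-kB, YAP, mesenchymal, antioxidant, chaperone and ribosomal lists passed as higher too. A shared direction in 1 comparison does not show a shared cause, and the part of RNA handling in these lists was not tested. JUN rose 2.33-fold (1.22 ± 0.06), and the metal-binding metallothioneins MT2A and MT1X rose 2.14-fold and 1.73-fold (SDs of 0.03 and 0.04 on the log2 scale). Of 23 NRF2 antioxidant genes, 13 rose and 3 fell, or 14 and 6 adjusted over the list alone (median 0.10, camera adjusted p = 0.0164; adjusted p = 0.367 with an estimated correlation). This median lay within the central 95% of 10000 random lists matched on intensity and GC (-0.079 to 0.103). The leading members of the antioxidant list were HMOX1, heme oxygenase 1, at 2.09-fold (1.06 ± 0.03), FTH1, ferritin heavy chain, at 1.86-fold (0.90 ± 0.02), and OSGIN1 at 1.58-fold (0.66 ± 0.08). Of 20 ER chaperone and unfolded protein genes, 13 rose and 1 fell, with the same counts adjusted over the list alone (median 0.19, camera adjusted p = 2.73e-04; adjusted p = 0.263 with an estimated correlation). HSPA5, the ER chaperone BiP, rose 1.53-fold (0.61 ± 0.05), CALR rose 1.52-fold (0.60 ± 0.03) and SDF2L1 rose 1.46-fold (0.54 ± 0.02).

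Ribosomal protein genes were higher, a call lost with Agilent's processed signals, and oxidative phosphorylation genes were lower, a direction that turned with median centring. Of 40 ribosomal protein genes, 36 rose and 2 fell, with the same counts adjusted over the list alone and a median log2 ratio of 0.27 (limma camera adjusted p = 6.73e-09; adjusted p = 0.263 with an estimated correlation). RPS2 rose 1.82-fold (0.86 ± 0.03) and RPS18 1.62-fold (0.70 ± 0.02). With Agilent's processed signals the list median was 0.014 and the call was lost (camera adjusted p = 0.353), with 13 genes higher and 5 lower. Those signals differ in background correction, detrending and dye normalization together, so the step behind the loss was not separated. With median centring the median was 0.99. The 100 brightest genes, of which 50 were ribosomal protein or metallothionein genes, had a median of 0.42 after loess and of 0.19 with Agilent's processed signals. Of 35 oxidative phosphorylation genes, 22 fell and 3 rose, or 25 and 3 adjusted over the list alone (median -0.12, camera adjusted p = 3.64e-05; adjusted p = 0.263 with an estimated correlation). SDHD, NDUFB10 and ATP5MC1 had log2 ratios of -0.35 ± 0.01, -0.35 ± 0.04 and -0.27 ± 0.01, and all 3, like the list (median 0.46), turned positive with median centring. With Agilent's processed signals the list stayed lower (median -0.13, 23 fell and 0 rose, camera adjusted p = 1.53e-05). Ribosomal protein, metallothionein and ferritin values are uncertain because transcripts of paralogs and pseudogenes can bind the same probes.

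**Figure D2:**
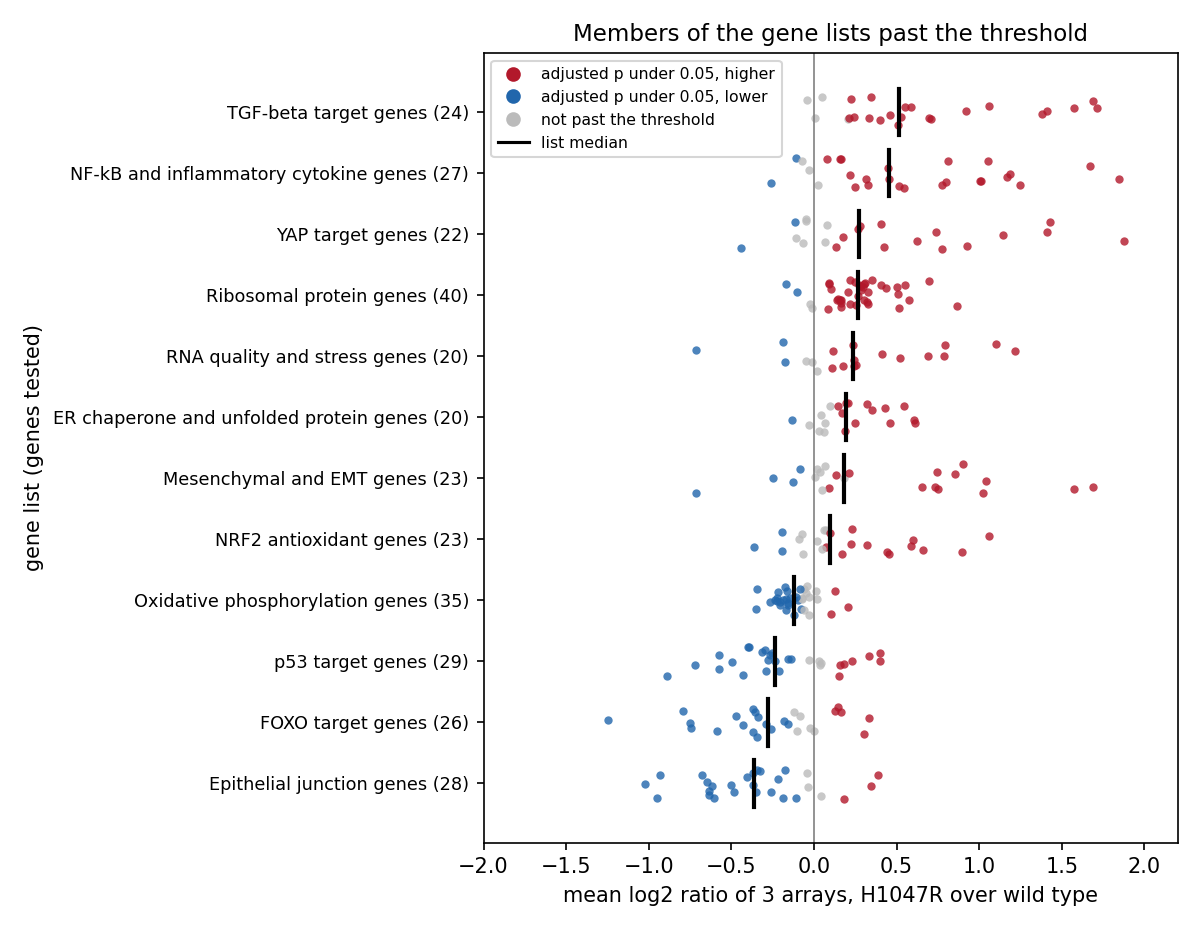
Mean log2 ratio over 3 arrays of each tested member (points) of the 12 gene lists past the camera threshold, with the number of genes tested in brackets and the list median as a black bar; red and blue points passed limma's adjusted p threshold and grey points did not. Medians run from -0.36 (epithelial junction genes) to 0.52 (TGF-beta target genes). The ribosomal list lost its call with Agilent's processed signals and the mesenchymal list with median centring, under which the medians of the FOXO, p53 and oxidative phosphorylation lists were positive. None of the 12 passed with an estimated correlation.

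Stem cell, basal, luminal and keratinocyte genes changed in both directions and their lists did not pass. Of 20 stem cell and progenitor markers, 9 rose and 7 fell, or 10 and 9 adjusted over the list alone (median log2 ratio 0.11, limma camera adjusted p = 0.66). SNAI2, a transcription factor of mammary progenitors and EMT, rose 1.68-fold (0.75 ± 0.01), ALDH1A3, an aldehyde dehydrogenase used as a marker of mammary progenitors, rose 1.65-fold (0.73 ± 0.03), and MYC fell 1.53-fold (-0.62 ± 0.01), a call lost with median centring. Of 26 basal epithelial genes, 11 rose and 11 fell, or 11 and 12 adjusted over the list alone (camera adjusted p = 0.89), with KRT6B and LAMB3 (2.16-fold, 1.11 ± 0.02) at one end and KRT15 at the other. Of 15 luminal genes, 5 rose and 5 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.898). Its leading members were KRT7 at 2.18-fold (1.12 ± 0.04), ALDH1A3 and TFF3 at 1.52-fold (3.68-fold with Agilent's processed signals), the last of these above background in wild type on 1 array. Of 21 keratinocyte differentiation genes, 7 rose and 8 fell, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.898). CRCT1 rose 2.68-fold (1.42 ± 0.09), or 7.27-fold with Agilent's processed signals, SPRR2A rose 2.44-fold (1.29 ± 0.09, uncertain among near-identical SPRR2 paralogs), and KRT13 fell.

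Growth factor and proliferation genes also went both ways. Of 49 proliferation genes, 16 rose and 16 fell, or 17 and 16 adjusted over the list alone (limma camera adjusted p = 0.892), with RRM2 at 1.61-fold (0.68 ± 0.02), E2F8 at 1.49-fold and CCNE2 at 1.42-fold. The median of this list was -0.0040, its mean was 0.03 and its test pointed down; with median centring it passed as higher (median 0.46, adjusted p = 9.17e-04). Of 21 ERK feedback and immediate early genes, 10 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.575). JUN led the rises with FOSL1, an AP-1 subunit, at 1.75-fold (0.81 ± 0.02), while DUSP6, an ERK phosphatase, fell 1.83-fold (-0.87 ± 0.05). Of 11 EGF family ligands and receptors, 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.521), with NRG2 at a log2 ratio of -1.22 ± 0.15, EREG at 1.51-fold and AREG at 1.38-fold. Of 21 matrix proteases and inhibitors, 11 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.39), and PLAU, the urokinase gene, rose 2.42-fold (1.27 ± 0.0035) with SERPINE2 at 1.81-fold.

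Lipid synthesis genes were mostly lower without passing the list test in the main fit. Of 19 fatty acid synthesis genes, 12 fell and 6 rose, the same adjusted over the list alone (median log2 ratio -0.16, limma camera adjusted p = 0.0766). With median centring its median turned positive (0.22), and it passed as lower than the other genes (adjusted p = 0.0239), as it did without the filter on dim probes (0.0141). Without its member shared with another list it passed as lower too (camera adjusted p = 0.0346, median -0.23). SREBF1, the transcription factor gene for lipid synthesis, fell 1.96-fold (-0.97 ± 0.02), ACSS2 fell by 0.68 ± 0.05 on the log2 scale and ACACA, acetyl-CoA carboxylase, fell 1.53-fold (-0.62 ± 0.03). Of 24 cholesterol synthesis genes, 13 fell and 3 rose, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.0552; past the threshold as lower without the offset, without the filter and without replicate 1, at 0.0464, 0.0141 and 0.0482). MVK and PMVK had log2 ratios of -0.35 and -0.27, which turned positive with median centring, as did the list (0.36), and STARD4 rose 1.22-fold. Of 35 ATF4 and amino acid genes, 16 fell and 7 rose, or 17 and 9 adjusted over the list alone (camera adjusted p = 0.235), although the members with the largest changes, CHAC1 (1.67-fold), DDIT3 (1.56-fold) and SLC7A11 (1.5-fold), rose. Of 31 MYC and ribosome biogenesis genes, 13 rose and 4 fell, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.0561; 0.0115 as higher without the filter on dim probes and 0.00108 with median centring), led by NPM1 (1.55-fold), ODC1 (1.45-fold) and RRP9 (1.22-fold). Of 25 glycolysis genes, 7 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.89; 0.0239 as higher with median centring, median 0.57), with SLC16A3 at 1.34-fold, PFKP at 1.26-fold and PFKFB4 at -0.29, positive with median centring. Of 23 hypoxia-response genes, 8 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.612), with ADM at 2.01-fold and LOXL2 at 1.58-fold beside ANGPTL4.

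Immune and developmental pathway lists did not pass in the main fit either. Of 28 interferon-stimulated genes, 7 rose and 9 fell, or 7 and 11 adjusted over the list alone (limma camera adjusted p = 0.551; 0.0267 as lower than the other genes with median centring, median 0.23); IFITM1 fell 1.59-fold, ISG20 fell 1.45-fold and GBP1 rose 1.55-fold. Of 20 complement and acute phase genes, 6 rose and 8 fell, or 6 and 9 adjusted over the list alone (camera adjusted p = 0.637), with C1S at 1.53-fold beside PTX3 and PLAU. Of 17 HLA and antigen presentation genes, 2 rose and 7 fell, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.198). HLA-F, B2M and PSMB9 had log2 ratios of -0.28, -0.25 and -0.17, all positive with median centring, and the PSMB9 call was lost with Agilent's signals (-0.12) and without replicate 2 (-0.13) or 3 (-0.18). Of 26 Wnt pathway genes, 9 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.892); the Wnt antagonist DKK1 rose 2.19-fold (1.13 ± 0.02), the receptor gene FZD4 fell 1.45-fold, and LRP6 had a log2 ratio of -0.31 that turned positive with median centring. Of 17 Notch pathway genes, 7 rose and 4 fell, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.994). NRARP and HES2 had log2 ratios of -0.38 and -0.34, calls lost with median centring, and HES5, above background in wild type on 1 array, one of 0.30, a call lost without the offset and with Agilent's signals (0.71 and 1.075), without the filter and without replicate 2 (0.22) or 3 (0.27). Of 16 histone genes, 7 rose and 3 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.39), with H4C3 at 1.53-fold, H2BC4 at 1.17-fold and H3C1 at -0.23, positive with median centring. The median and mean differed in sign in the basal (-0.02 and 0.08), luminal (-0.02 and 0.13), glycolysis (-0.0019 and 0.03), complement (-0.05 and 0.09) and Notch (0.02 and -0.0054) lists.

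Some genes were well above background in 1 dye only, and for these a ratio is a bound. In 140 genes the signal was above background in H1047R cells alone and in 62 genes in wild type alone. In H1047R cells the bound on the mean was 2.13-fold brighter for DEFB103B, a beta-defensin gene (limma adjusted p = 0.00177), 1.58-fold for ADAMTS6 (adjusted p = 4.56e-04) and 1.51-fold for OR5B3 (adjusted p = 0.00161). In wild-type cells the bound on the mean was 1.51-fold brighter for BLNK (limma adjusted p = 8.24e-04), 1.41-fold for ETV7 (adjusted p = 0.00614) and 1.35-fold for ELF3 (adjusted p = 0.00292). Agilent's processed signals, which hold surrogate values for dim spots, gave ratios from 3.80-fold (ELF3) to 12.9-fold (OR5B3) for these genes. The bounds make no allowance for the spread between arrays, and a single array can lie below them. DEFB103B had log2 ratios of 0.85, 1.22 and 1.25 on arrays 1 to 3. The bounds are also open to dye bias because the dyes were not swapped.

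Of the 36 lists, 12 passed camera with its preset correlation (8 higher, 4 lower), 16 had an unadjusted p under 0.05, and 34 passed limma's fry, which does not compare a list with other genes. With an estimated correlation 0 lists passed and 4 had an unadjusted p under 0.05, so no list call holds under that setting. Among the 12 lists the estimate exceeded 0.01 only for the cytokine (0.050), TGF-beta (0.018), NRF2 (0.036) and oxidative phosphorylation (0.037) lists. For the ribosomal list the estimate (0.0024) was below 0.01, yet its unadjusted camera p went from 1.87e-10 to 0.0188. That setting rests on the few degrees of freedom that 3 arrays leave, so a loss under it does not show correlation within a list. With median centring 14 of the 15 list medians below 0 turned positive, all but that of the junction genes.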

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

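A signal appeared in control features that enter no comparison: 2 of 96 ERCC control probes were well above background in both dyes on all 3 arrays. Their mean signals were 43.9 and 56.0 in Cy3 and 67.6 and 99.1 in Cy5. The median signals of the arrays were 47.0 to 48.4 in Cy3 and 73.05 to 76.6 in Cy5, so the first probe lay below them and the second above them. In Cy5, 2.99% of ERCC features were above background, against 0.433% of the negative control features. Neither the labels nor the file headers used here say whether ERCC transcripts were added.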

How the results depend on the processing

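The 1.5-fold threshold, limma's treat and the lists without shared members were chosen after the data were seen. Agilent's processed signals and the series table gave the same values. The totals below count them as separate alternatives, and so hold each of their results under both names. PTX3 kept its direction and its call in all 16 alternatives, with log2 ratios from 1.83 to 2.21 (highest adjusted p = 0.00751). For the named genes, 1832 of the alternative values kept direction and call, 19 lost the call and 13 changed sign; for lists, 560 kept their side of the threshold, with the same direction where they passed, 10 gained the call, 3 lost it and 3 passed in a turned direction of the list test, which compares a list with the other genes. The 9495 changed genes became 14803 with median centring, 101 with a 2-fold threshold, 539 with a 1.5-fold threshold, 192 by treat against 1.5-fold, and 6693 to 6939 without 1 replicate, where 1 fewer array was fitted. Without the array as a replicate block, in a fit of separate channels, 8816 genes passed and no call of a named gene or list was lost. The 101 genes changed by at least 2-fold became 239 without offset, 373 with Agilent's processed signals or the series table, and 379 with median centring, and all 101 kept their direction and an adjusted p under 0.05 in each, though not always a 2-fold change (11 genes were lower by 2-fold with median centring, against 33). Of 12 lists past the threshold, 0 passed with an estimated correlation and 34 by fry, which asks another question; 12 to 13 passed without 1 replicate, and 13 when members held by several lists were left out. Median centring leaves the intensity trend between the dyes and moved the median of all genes to 0.30. Under it the log2 ratio turned positive for PIK3CA (0.20), PSMB9 (0.21), H3C1 (0.30), B2M (0.30), ATP5MC1 (0.26), PMVK (0.18), HLA-F (0.18), PFKFB4 (0.020), LRP6 (0.070), NDUFB10 (0.20), MVK (0.19), SDHD (0.10) and FBLN1 (0.065). The list test turned for proliferation (median 0.46), cholesterol synthesis (0.36) and oxidative phosphorylation genes (0.46), while 14 of the 15 list medians below 0 became positive, FOXO (0.052) and p53 (0.16) targets among them. Apart from FBLN1, PFKFB4 and LRP6, the genes with a turned ratio passed the threshold as higher. The ribosomal list lost its call with Agilent's signals and the series table (median 0.014, adjusted p = 0.353, the highest of all alternatives, which began at 2.08e-14). The processing step behind that loss was not separated, and the cause of the other changes was not tested. Signal over background limits dim genes: genes measured in 1 dye, 140 in Cy5 and 62 in Cy3, have bounds only, and folds of dim genes grow when the offset is left out.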

Other observations

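The symbol families and the second-probe, spot-noise and bright-spot tests were chosen after the data were seen. Among 174 families of genes with a shared symbol stem and at least 10 tested members, 5 passed: the ribosomal RPS (33 of 45 rose and 8 fell, median 0.19) and RPL (43 of 63 rose and 9 fell, median 0.17) genes, treated below as a list, and 3 others; none passed with an estimated correlation (adjusted p = 0.958 for RPS and RPL). Of 10 metallothioneins, 9 rose and 0 fell, with a median log2 ratio of 0.74 (limma camera adjusted p = 2.49e-04; adjusted p = 0.958 with an estimated correlation). Transcripts of paralogs and pseudogenes can bind the same probes, so these 10 genes may not be separate measurements, while the test counts them as such. MT2A rose 2.14-fold and MT1L 1.88-fold, MT1A and MT1B 1.81-fold, and MT1F did not pass (-0.013). With Agilent's processed signals the median was 0.53 and 9 still passed as higher, and with median centring it was 1.45. MT2A, MT1L, MT1A and MT1B were among the brightest genes (mean log2 intensity 17.13 to 17.71), while MT3, which rose too, was at 12.69.

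Aldehyde dehydrogenase genes went against ALDH1A3. Of 14 tested, 9 fell and 1 rose (median -0.23, limma camera adjusted p = 0.0317; adjusted p = 0.958 with an estimated correlation). ALDH1A3 was the member that rose, while ALDH6A1 fell 1.55-fold (-0.64 ± 0.08, SD, n = 3), ALDH3A1 1.49-fold (-0.57 ± 0.05) and ALDH3A2 1.36-fold (-0.45 ± 0.02). The median was -0.27 with Agilent's processed signals and 0.087 with median centring, where 7 rose and 3 fell. Of 38 keratin-associated protein genes, 14 rose and 0 fell (median 0.10, camera adjusted p = 0.0317, or 0.958 with an estimated correlation), led by KRTAP19-5 at 1.37-fold and KRTAP12-2 at 1.34-fold. Their median was 0.18 with Agilent's processed signals. Without 1 replicate, 7 to 9 rose and up to 2 fell, and without the filter on dim probes 7 rose. With median centring 32 rose (median 0.30), and with a filter in both dyes 13 of 34 rose. Of all tested genes, 51.5% were called. Olfactory receptor genes went the same way without passing (14 of 45 rose and 1 fell, camera adjusted p = 0.22). KRTAP10-2 was above background in Cy5 alone, and whether signals near background gave these calls was not tested.

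The first pattern is that 51.5% of the tested genes passed the threshold, mostly with small changes, on 3 arrays that hardly differed. With spot position removed, the arrays differed beyond spot noise in 4.29% of 606 probes (exact binomial 95% interval 2.82% to 6.22%), and in 0 of them after adjustment. Repeat hybridisations of 1 pair of RNAs would give this, although very uniform cultures stay possible. The tables argue against a GC trend, since 97.4% of called genes kept call and direction after it was removed. Dye bias of single probes was tested through second probes: the same sign was seen in 90.8% of genes called at 1.5-fold or more, where bias alone would give about 50%, and in 73.2% of genes called below that (exact binomial 95% interval 71.3% to 75.0%), which argues against it as the whole cause of either; the part it has in them, and dye bias shared by the probes of a gene, stay open without a dye swap. Turning the sign of arrays gives 4 patterns, too few for a share under 0.05; the real one, the 1 with as many, called 9495 genes and 12 lists, and the highest other called 0 genes and 5 lists.

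The higher ribosomal protein genes and lower oxidative phosphorylation genes are the second pattern. The ribosomal median fell from 0.27 to 0.014 with Agilent's processed signals. A dye effect at the brightest spots would give such a fall, but background correction and detrending changed together with the dye normalization, so the fall cannot single it out. Among 10000 random lists matched on intensity and GC the ribosomal median lay at percentile 0.12, below their median of 0.37, so it was no higher than other genes of that brightness. The oxidative phosphorylation median of -0.12 lay at percentile 0 of its matched lists, whose lowest was -0.11, which argues against a bias set by intensity and GC alone; bias of single probes and an effect of H1047R stay open, and the sign turned with median centring (0.46).

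Copy number differences between the pools are the third pattern looked for. Of 15969 windows of 101 neighbouring genes (18269 genes in all, by hg19 position), 0 had a median log2 ratio beyond the most extreme of 1000 shuffles of gene order. The highest window median was 0.08, on chromosome 19 from 50093697 to 54544173, and the lowest was -0.06, on chromosome 3 from 44764280 to 50362447, against shuffle extremes of 0.12 and -0.09. This argues against a large gain or loss behind the changes; smaller ones than a window were not tested.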
